A study of Solanum lycopersicum with 8 samples.

How the data were processed

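RNA from tomato fruit pericarp was measured on 1-colour (Cy3) Agilent tomato expression arrays in 2 genotypes, wild type and the Tangerine2 mutant, at 4 stages (mature green, breaker, turning and ripe). Each genotype and stage had 1 array, 8 in all. The labels state that tissue of each sample was prepared several times over, but only 1 array stands for each group. The protocol text of the wild-type samples describes cultivar Arka Vikas beside a high-beta-carotene mutant, so these arrays appear to have been described with another mutant study as well. The growth and dissection protocols are otherwise alike.

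The deposited value table holds log2 signal per array accession, from which the authors had subtracted each array's 75th percentile. Per the file headers, the scanner files of the 4 Tangerine2 arrays hold intensity values, background-subtracted and detrended by Agilent Feature Extraction 11.5.1.1 and not scaled between arrays. The deposited scanner files also carry a yes-or-no mark per spot for a signal well above background (other unit, per the file headers). The 4 Tangerine2 arrays were read in 1 scan of 1 slide. Scanner files of the wild-type arrays were not analysed here, so genotype and slide cannot be separated.

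How the value table was made was checked on the Tangerine2 arrays. For 100% of accessions it equalled, within a tolerance of 0.02, the mean log2 signal over spots well above background (over all spots where none was) minus a constant of 9.69, 9.27, 8.32 and 8.47 for mature green, breaker, turning and ripe fruit. The rule was taken to hold for wild type. For 1646 accessions with several probes the set of averaged probes therefore changed between Tangerine2 arrays. Whether it also changed between wild-type arrays could not be seen, so remarks on changing probes cover Tangerine2 only. No signal was saturated.

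A gene here is an array accession, of which there were 40387, covered by 50200 probes on 61657 spots. Of these, 34190 had 1 probe and 6197 had several, and a gene can have several accessions. In the reference table of assembly SLM_r2.1, 1052 accessions had a match and took its symbol, and 4289 had a named product. Signal was well above background on all 4 Tangerine2 arrays for 22473 accessions, on at least 1 array for 30005 and on none for 10382. The lowest value at which signal was told from background was -5.99, -5.84, -4.97 and -4.70 on the table's log2 scale for the 4 Tangerine2 stages in order. The wild-type arrays have no such limit of their own here and were given the highest, -4.70. Folds against a group with arrays below these limits are given as "at least", with values below the limit raised to it. For Tangerine2 single arrays this was done probe by probe where an accession had several, a step added after the data had been seen.

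Tests were run on the value table with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and Benjamini-Hochberg adjustment over 40387 accessions, with a threshold of 0.05. The genotype difference was fitted with stage as a factor. Stage differences against mature green came from a fit of stage with genotype as a term. Both fits left 3 residual degrees of freedom, with 2.45 added by the prior. The difference between genotypes in the slope over stages coded in order was fitted with 4 residual degrees of freedom. Because no group has replicate arrays, the p-values of these fits rest on how far a difference varied between stages or between genotypes.

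Differences between single arrays have no replicate check and carry no test. They are given as sizes, and genes at least 2-fold apart were counted. For Tangerine2 stages these came from the scanner files: log2 processed signal, averaged over all probes of an accession, minus the array's 75th percentile, for accessions well above background on at least 1 of the arrays compared. Other single-array differences came from the value table.

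There were 17 gene lists, of which 16 had several measured members. Planned members that could not be matched by name were left out, so lists cover their pathways in part. The carotenoid pathway had 13 measured members, MEP and prenyl supply 7 and the flavonoid list 7. They were carotenoid pathway, carotenoid cleavage and abscisic acid, MEP and prenyl supply, ethylene, ripening regulators, cell wall softening, flavonoid, flavour volatiles, sugar with starch and acids, chlorophyll breakdown, light harvesting, cytosolic ribosomal proteins, heat shock, histones, seed contents, epidermis and cuticle, and pathogen and wound response. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. In single-array differences the median of a list was ranked among 10000 random lists of the same size and mean signal. Members of a random list were drawn independently, so genes that move together reach extreme percentiles more easily. The counts "adjusted over the list alone" use only the members of a list.

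The lists, tests, filters and alternatives were chosen before the data were examined, except where said otherwise. The rule for naming genes was fixed then too. It took up to 10 rises and 10 falls with a named product that passed each test and went the same way everywhere, and the 5 smallest p-values in each direction where none passed. It also took the 5 largest rises and falls between single arrays, up to 4 members of each list, and all of the carotenoid pathway. The carotenoid isomerase CRTISO had no accession that could be matched by name and is not analysed here.

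On simulated data of the same size, with 50 changed genes per size, the genotype fit recovered 4% of genes changed by 2 on the log2 scale, 72% at 4 and 98% at 8, with 2 false calls. The ripe against mature green fit recovered 2%, 26% and 84%, with 3 false calls. The slope fit recovered 50%, 84% and 96%, with 11 false calls, but its simulated changes of 2, 4 and 8 were per stage. They add up over the stages, so its shares cannot be set beside those of the other fits. None of the fits recovered a change of 1, again per stage for the slope. A simulated list of 20 genes shifted by 1 ranked at percentile 99.94 and an unshifted list at 12.95.

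Alternatives were median centring, quantile normalization, filters on dim accessions, a trended and robust prior, fits without stage or genotype terms, stage as a linear term, each array or stage left out, and normexp background correction (offset 50). A filter on the mean over the 8 columns, values below detection raised to the limit, and accessions with 1 probe were added after the data had been seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.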

Results

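Gene expression was measured in pericarp of wild-type and Tangerine2 tomato fruit at 4 stages of ripening, with 1 array for each of the 8 combinations. Tangerine fruit are orange, and the tangerine locus is known for the carotenoid isomerase CRTISO, which acts between the desaturases and lycopene. Signal was brighter in the younger Tangerine2 samples: the 75th percentile of processed signal was 946.8 at mature green, 739.5 at breaker, 369.0 at turning and 404.9 at ripe. The share of spots well above background was 70.1%, 69.4%, 63.3% and 60.4% in the same order, so weakly expressed genes were measured less well in the later Tangerine2 samples. Across genes, which are not independent, the arrays of both genotypes correlated at 0.957, 0.967, 0.937 and 0.951 at the 4 stages in order. Turning and ripe Tangerine2 fruit correlated at 0.977. The Tangerine2 breaker array correlated at 0.937, 0.967, 0.965 and 0.949 with the wild-type arrays from mature green to ripe. With the Tangerine2 mature green, turning and ripe arrays it correlated less, at 0.928, 0.933 and 0.932. Turning Tangerine2 fruit correlated at 0.945 with ripe wild type. The number of arrays limits the precision of every difference.

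The comparison of ripe with mature green fruit asked which genes follow ripening in both genotypes. Polygalacturonase, the enzyme that takes apart pectin in softening fruit, led the rises. Its records rose by up to 10.75 ± 0.80 on the log2 scale (log2 difference ± SE, 2 arrays per stage, adjusted p = 0.011), at least 359-fold because both mature green values lay below the detection limits. PG-2a rose by 9.13 ± 0.42 (adjusted p = 0.0109) and PG2A, whose averaged probes changed between arrays, by 8.92 ± 0.76 (adjusted p = 0.0126). Proteinase inhibitor ER1 rose by 7.43 ± 1.02 (adjusted p = 0.0271), a proteinase inhibitor I-like record by 7.60 and at least 169-fold, and a MADS-box factor, LOC778231, by 6.85 ± 1.12 (adjusted p = 0.0362). Alcohol acyl transferase, which makes the esters of fruit aroma, rose by 7.02 and at least 51.2-fold in one record and by 6.96 (adjusted p = 0.0343) in AAT, whose averaged probes changed too.

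The largest named falls included genes of cell division, photosynthesis and sugar import. A histone H4 record fell by 8.77 ± 1.05 (adjusted p = 0.0207), at least 136-fold. Light-dependent protochlorophyllide oxidoreductase, which makes chlorophyll, fell by 8.55 and by 8.10 in its records, at least 58.7-fold and 80.1-fold. A light-harvesting chlorophyll a/b protein fell at least 231-fold, glycolate oxidase LeGLO2 of photorespiration at least 144-fold, and a non-specific lipid-transfer protein at least 250-fold. The invertase records LIN6 and Wiv-1, whose values were nearly the same on all wild-type arrays, as those of 1 gene would be, each fell at least 72.9-fold. AroGP2, a non-catalytic polygalacturonase subunit, fell at least 60.3-fold and Hsr201 fell by 8.27 ± 0.32, at least 45.3-fold.

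In all, 2077 accessions passed (limma, Benjamini-Hochberg), 702 higher and 1375 lower in ripe fruit. The excess of falls depended on the processing: 33.8% were higher, against 49.0% with median centring, 50.6% with signal well above background on all 4 Tangerine2 arrays and 63.9% with linear stage. The median of all accessions was 0.40, which moved to 0.63 with median centring and 0.12 with quantile normalization, where 1233 passed. The calls in ripe fruit did not hold without the wild-type ripe, Tangerine2 mature green or Tangerine2 ripe array. Some held without the wild-type mature green array, and more without either breaker array. Each of these fits leaves a stage with 1 array, so the loss concerns the calls, and whether the changes themselves rest on these arrays was not shown.

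Within the carotenoid pathway, phytoene synthase PSY1, the gate to fruit carotenoids, rose in ripe fruit by 4.45 ± 0.54 (adjusted p = 0.021) and the lycopene epsilon-cyclase LCYE, which leads to lutein, fell by 4.53 ± 0.79 (adjusted p = 0.0418), at least 3.85-fold. Over the whole list 1 member rose and 1 fell, against 6 higher and 1 lower adjusted over the list alone. The further members higher by that measure were the desaturases PDS at 1.70 and ZDS at 1.50, the hydroxylases BCH1 at 1.96 and BCH2 at 1.41, and PSY2 at 1.45. PSY1, PSY2, PDS, LCYB1 and VDE were averaged over changing probes, and with all probes averaged the Tangerine2 ripe and mature green arrays differed by 5.72, 0.33, 1.55, -1.88 and -0.93, some of their probes being below detection on an array. The other values were -1.36 for CYCB, -0.36 for LCYB1, 0.03 for CYP97A29, -1.07 for CYP97C11, -1.12 for ZEP and 1.06 for VDE. The list as a whole had a median of 1.06 and a mean of 0.39 and was not apart from other genes (camera adjusted p = 0.746).

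The supply of precursors moved unevenly. GGPS2, which makes the substrate of phytoene synthase, rose by 3.90 ± 0.49 (adjusted p = 0.0227); HDR at 1.45 was higher and IPI at -2.86 and GGPS1 at -2.16 were lower adjusted over the list alone, GGPS1 with no fold to state because its ripe values lay below the detection limits. Over all genes 1 member of this MEP and prenyl list passed, against 2 higher and 2 lower adjusted over the list alone (median 1.15, camera adjusted p = 0.755). The table values of DXS1, the entry enzyme, cannot be compared between arrays because its averaged probes changed: they were 3.45, 0.14, 4.33 and 4.43 in Tangerine2, while its bright probe, well above background on all 4 arrays, was 3.25, 4.16, 4.12 and 4.24 minus the array's 75th percentile. Carotenoid cleavage and abscisic acid genes had a median of 0.31 and 0 members passed (limma; camera adjusted p = 0.755).

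Genes that make ethylene, the ripening hormone, were among the rises. The synthases ACS2 and ACS4 rose by 4.44 ± 0.79 (adjusted p = 0.0439) and 3.57 ± 0.33 (adjusted p = 0.0136, at least 8.86-fold); ACS4 was averaged over changing probes. Over the ethylene list 2 members rose and 1 fell, against 4 higher and 2 lower adjusted over the list alone, and the list median was 0.50 (camera adjusted p = 0.745). Among the regulators, the MADS-box factor RIN rose by 6.63 ± 1.16 (adjusted p = 0.0421) and the NAC factor NOR by 4.12 ± 0.59 (adjusted p = 0.0291). FUL1 at 1.54 and AP2a at 2.62 were higher, and the chloroplast regulator GLK2 at -1.93, with ripe values below the detection limits, lower, adjusted over the list alone (4 higher and 1 lower, against 2 and 0 over all genes; median 1.14, camera adjusted p = 0.229).

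Softening genes stood out as a group in ripe fruit, with a median of 2.64 over 8 members (camera adjusted p = 0.0385; adjusted p = 0.705 with an estimated correlation). Besides PG2A, the beta-galactosidase TBG4 at 1.84, the glucanase CEL2 at 3.44, XTH5 at 1.75 and the mannanase MAN4A at 6.68 (at least 33.1-fold) were higher adjusted over the list alone (5, against 1 over all genes), and expansin EXP1 differed by 3.85 without passing. TBG4, CEL2 and MAN4A were averaged over changing probes, and the list call was lost without the wild-type mature green array (adjusted p = 0.10). Lipoxygenase LOXC, which opens the route to leaf-alcohol volatiles, rose by 6.34 ± 0.64 (adjusted p = 0.0159, at least 36.8-fold), and LOXB at 3.09 was higher adjusted over the list alone (2, against 1 over all genes; list median 0.69, camera adjusted p = 0.381).

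Starch and sucrose genes lay lower in ripe fruit, with a median of -1.55 (camera adjusted p = 0.0385; adjusted p = 0.705 with an estimated correlation). Sucrose synthase SUS1 fell by 4.02 ± 0.56 (adjusted p = 0.0276, at least 10.1-fold) and AGPL1, a subunit of the starch-making ADP-glucose pyrophosphorylase, by 4.16 ± 0.70 (adjusted p = 0.0389, at least 4.04-fold). AGPL3 at -3.58 (at least 10.3-fold) and glutamate decarboxylase GAD3 at -2.63 (at least 2.37-fold) were lower and the vacuolar invertase VI at 3.85 higher adjusted over the list alone, which gave 1 higher and 4 lower against 0 and 2 over all genes. The list call was lost with quantile normalization (adjusted p = 0.137), without the wild-type mature green array (0.116), without either breaker array (0.0589) and without the Tangerine2 ripe array (0.057). AGPL1 was averaged over changing probes.

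Genes of chlorophyll and photosynthesis moved only in part. SGR1, which starts chlorophyll breakdown and was the only measured member of its list, rose by 4.58 ± 0.69 (adjusted p = 0.0318). The light-harvesting proteins CAB7 and CAB8 fell by 5.73 and 5.44, and a Rubisco small subunit record by 6.35 (adjusted p = 0.033, 0.04 and 0.0342), the last at least 13.1-fold. Over 71 light harvesting and photosystem accessions 4 fell, against 13 adjusted over the list alone, with a median of -0.25 and a mean of -1.28 (camera adjusted p = 0.000454; adjusted p = 0.705 with an estimated correlation). In wild type alone the ripe median was 0.13 (percentile 12.05), with nuclear records at -0.48 (percentile 0) and plastid records at 0.41 (82.17).

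Histones, needed while cells divide, lay lower in ripe fruit with a median of -0.49: H3 fell by 7.08 and at least 19.3-fold, a further H4 record by 6.09 and H2B-1 by 4.79, among 4 members over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00551; adjusted p = 0.705 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.39 with 0 members passing in limma over all genes or over the list alone (camera adjusted p = 0.00705; adjusted p = 0.773 with an estimated correlation), a call lost without the Tangerine2 mature green array (0.254) or the Tangerine2 ripe array (0.057). Heat shock proteins went both ways: plastid HSP21 rose by 5.08 ± 0.81, vis1 by 3.71, HSP70 by 2.57 and er-sHSP by 2.25, while TFHS1 fell by 3.11 (6 up and 2 down, against 8 and 2 adjusted over the list alone; median 0.77, camera adjusted p = 0.229).

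Some defence genes fell in ripe fruit and some rose. Pathogenesis-related leaf protein 6 fell by 7.46 and at least 52.1-fold, a record of STH-2 by 6.63, the proteinase inhibitor CEVI57 at least 45.6-fold and records of pathogenesis-related protein 4 at least 19.9-fold and 23.8-fold. The subtilase P69G fell by 2.66 with no fold to state, its ripe values being below the detection limits. The list held 2 rises and 6 falls, against 3 and 10 adjusted over the list alone (median -0.79, camera adjusted p = 0.0246; adjusted p = 0.705 with an estimated correlation), and the call was lost without the wild-type mature green array (0.326) or the wild-type ripe array (0.15). The remaining lists were not called: flavonoid genes had a median of 1.52 (camera adjusted p = 0.655), seed contents 0.84 (0.755; an oleosin record fell by 3.07, at least 4.29-fold) and epidermis and cuticle -3.90 (0.229), where CD2 at 2.70 was higher and a lipid-transfer protein at -7.70 lower adjusted over the list alone. Camera sets a list against all other accessions, so carotenoid cleavage, with a median of 0.31 and a mean of 0.04, ran in the lower direction.

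**Figure D1:**
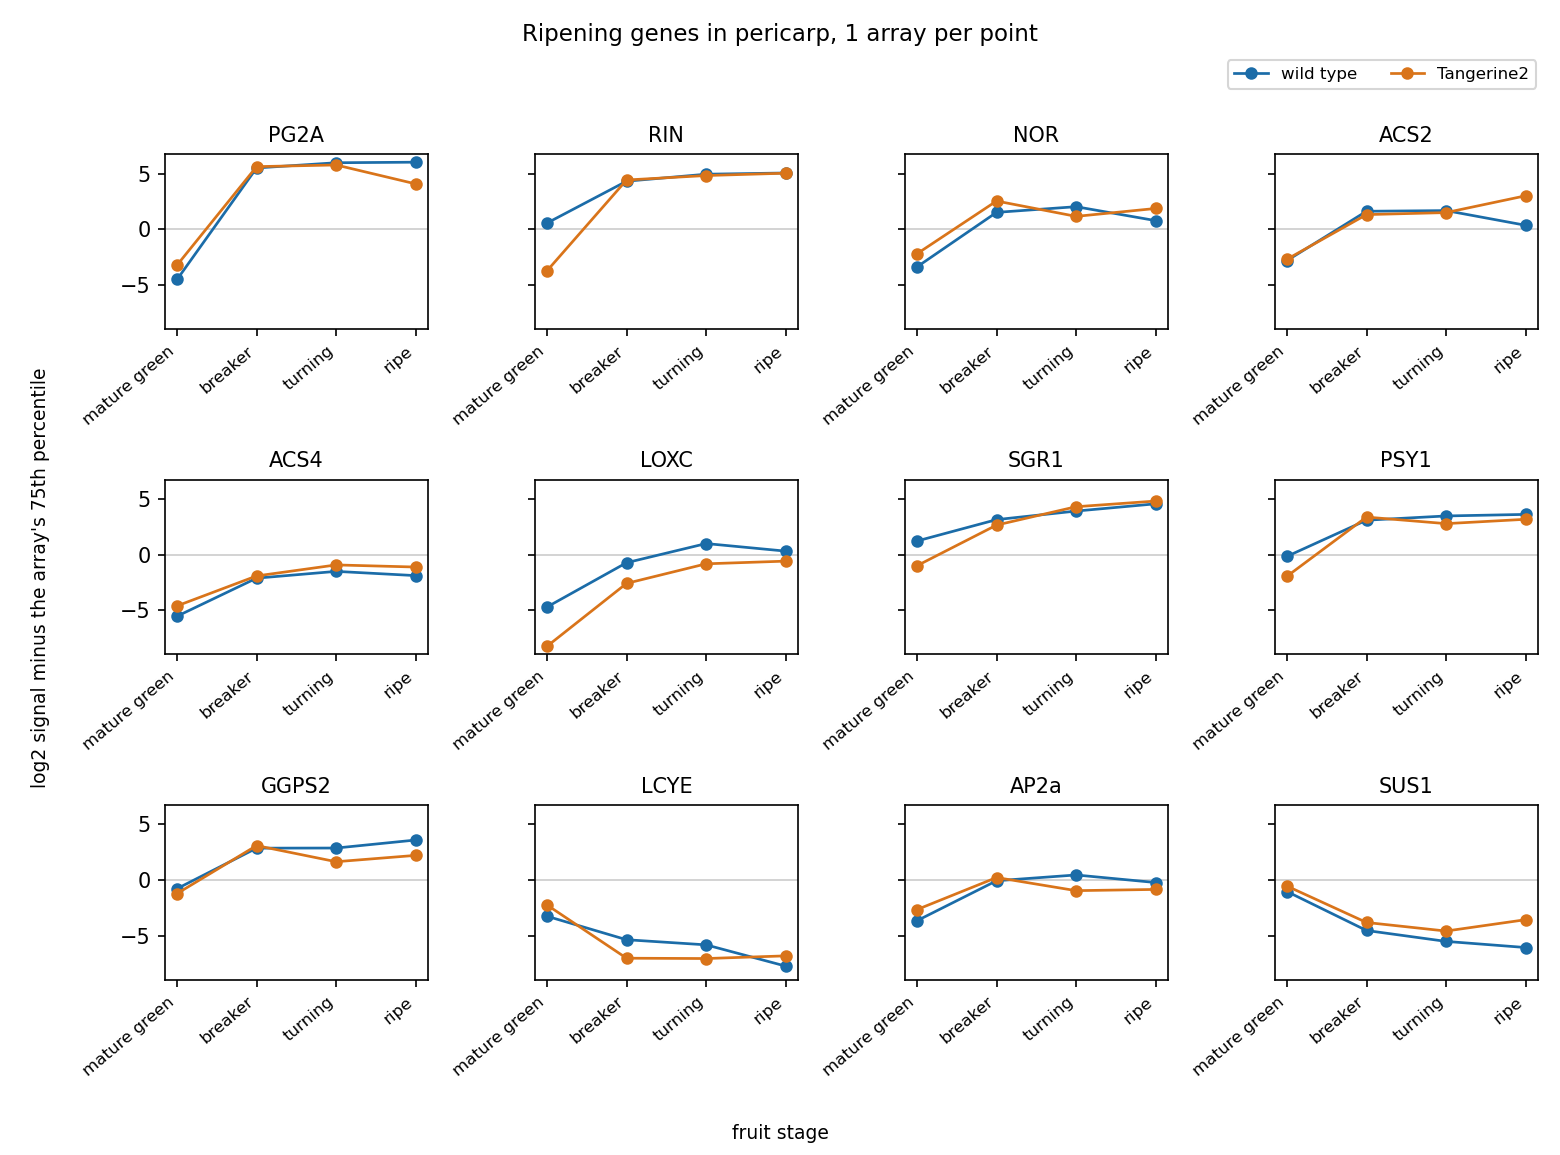
Log2 signal minus the array's 75th percentile (vertical) by stage (horizontal) for 12 ripening genes, with wild type in blue, Tangerine2 in orange and 1 array per point. RIN was 0.55 in wild type and -3.74 in Tangerine2 at mature green, and 5.05 and 5.03 in ripe fruit.

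The breaker and turning stages, set against the same mature green arrays, asked how early ripening genes move. Polygalacturonase was already high: at breaker a record rose at least 603-fold and PG2A by 9.44 ± 0.76 (adjusted p = 0.0208), and at turning the same record rose at least 614-fold and PG2A by 9.75. Beta-galactosidase records named STBG4 and TBG4, with nearly the same values on every array, rose at breaker by 5.60 ± 0.49 (adjusted p = 0.0249) and 5.55, the cytokinin oxidase CKX7 at least 7.74-fold and an alcohol acyl transferase at least 34.9-fold. PSY1 rose by 4.29 at breaker (adjusted p = 0.0453) and 4.18 at turning (adjusted p = 0.0386), NOR by 4.82 and 4.38, ACS4 at least 6.19-fold and 10.8-fold, and GGPS2 by 3.98 and 3.26. At turning a further ACS record rose at least 61.2-fold and LOXC at least 42.8-fold.

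Among the early falls, IAA2, an auxin-response repressor, fell at least 40.3-fold at breaker and 29.8-fold at turning, the jasmonate-linked LEJA1 at least 66.7-fold and 49.3-fold, and AroGP2 at least 89.7-fold and 66.3-fold. At breaker ODD fell at least 16.0-fold and Lsi-1 at least 12.9-fold. Protochlorophyllide oxidoreductase fell at least 64.5-fold at turning, the xyloglucan transferase XTH1 at least 102-fold and GPAT4, an acyltransferase of cutin synthesis, at least 38.7-fold. At breaker 330 accessions passed (91 higher, 239 lower) and at turning 733 (220 higher, 513 lower). The share higher at breaker, 27.6%, became 61.1% with signal well above background on all 4 Tangerine2 arrays, 56.2% with the mean filter and 61.4% without the wild-type mature green array; at turning it went from 30.0% to 47.6% and 45.8% with these filters. The breaker count was 114 without the wild-type mature green array and 0 without any other array (limma; 3808 to 5965 at an unadjusted p under 0.05). The turning count was 284 without the wild-type mature green array, 371 without either breaker array, 146 without either ripe array and 0 without either turning array or the Tangerine2 mature green array (limma; 7290, 5153 and 5023 unadjusted).

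Among the lists at breaker, softening genes had a median of 2.24 (camera adjusted p = 0.000316; adjusted p = 0.333 with an estimated correlation) and ripening regulators 1.19 (0.00239; adjusted p = 0.333 with an estimated correlation). Heat shock proteins had a median of 0.66 (0.00139; adjusted p = 0.44 with an estimated correlation), a call lost without the Tangerine2 breaker array (0.301). Flavonoid genes had a median of 2.63 (0.0345; adjusted p = 0.467 with an estimated correlation), lost without either mature green array (0.0819 and 0.0833), the Tangerine2 breaker array (0.586) or with quantile normalization (0.0853). Pathogen and wound genes had a median of -1.50 (0.00444; adjusted p = 0.467 with an estimated correlation), lost without the wild-type mature green array (0.224) or breaker array (0.068). Sugar and starch genes had a median of -0.76 (0.0233; adjusted p = 0.385 with an estimated correlation), lost without either mature green array (0.0605 and 0.0577) or the wild-type breaker array (0.0963). Ribosomal proteins had a median of -0.26 (0.011; adjusted p = 0.75 with an estimated correlation), lost without the wild-type breaker array (0.321) or the Tangerine2 mature green array (0.747).

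At turning 3 lists were called. Softening genes had a median of 2.11 (camera adjusted p = 0.0184; adjusted p = 0.527 with an estimated correlation), lost without the wild-type turning array (0.0713). Sugar and starch genes had a median of -1.66 (0.019; adjusted p = 0.527 with an estimated correlation), lost with quantile normalization (0.0632). Ribosomal proteins had a median of -0.43 (0.000485; adjusted p = 0.725 with an estimated correlation), lost without the Tangerine2 mature green array (0.117) or turning array (0.141). For light harvesting the median was 0.13, the mean -0.72 and the direction lower (0.176), and at breaker 0.14, -0.07 and higher (0.963). MEP and prenyl genes at 0.64 and flavonoid genes at 0.51 also ran in the lower direction at turning (0.933 and 0.999). Both medians lay above that of all accessions, 0.29, but camera compares test statistics rather than log2 differences.

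The genotype comparison asked which genes differ in Tangerine2 at all stages. A record of the 60S ribosomal protein L15 was lower in Tangerine2, at -9.80 ± 0.34 (4 arrays per genotype, adjusted p = 0.005), at least 455-fold: it ran from 3.39 to 3.88 in wild type and from -7.21 to -5.58 in Tangerine2. The other L15 records did not follow, with differences of 0.17, -0.11 and -1.43 ± 0.23 (adjusted p = 0.695, 0.837 and 0.151). A record of UPF0293, a family of unassigned function, was higher by 7.13 ± 0.34 (adjusted p = 0.0114), at least 13.1-fold with all wild-type values below the limit taken for them, -4.70, the highest of the Tangerine2 arrays. Of the 14 accessions that passed (9 higher and 5 lower, limma), 12 had no named product, with the lowest at -11.89 (at least 906-fold) and the highest at 8.07 (at least 22-fold). All 4 Tangerine2 arrays shared a slide, so genotype and slide cannot be told apart, and 0 passed in limma without the breaker or the ripe stage (8680 and 3594 at an unadjusted p under 0.05, against 8828 with all), 4 without mature green and 3 without turning. Among the 30005 accessions well above background on at least 1 Tangerine2 array, 4358 had such a p in limma. Many of the 8828 were thus dim. The floor (lowest percentile of values) was -8.32 in Tangerine2 against -8.6 in wild type at mature green, and -7.04 against -8.01 at ripe.

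Flavonoid genes had the largest list difference between genotypes, which again cannot be told apart from slide. Only a slide effect alike on all 4 Tangerine2 arrays would also have had to show at breaker. The 4 measured epidermis and cuticle genes were also lower (median -1.99) and at the same stages. Lipid-transfer protein records, which this list takes in, also changed with stage. They were at -7.64 and -7.56 in ripe against mature green wild type, while CD2 rose in ripe fruit. The list therefore does not measure the share of epidermis alone. Chalcone synthases CHS1 and CHS2, which begin flavonoid synthesis, and the hydroxylases F3H and F3'H differed by -3.31 ± 0.91, -3.98 ± 1.00, -2.52 ± 0.58 and -3.18 ± 0.82. None passed over all genes (adjusted p = 0.225 each), against 4 lower adjusted over the list alone (0.0223 each). CHS2 was 2.97, 4.15, 3.93 and 4.86 in wild type from mature green to ripe, and -2.10, 4.10, -1.20 and -0.83 in Tangerine2. Their regulator MYB12 was 0.64 and 1.86 in turning and ripe wild type and -4.55 and -3.58 in Tangerine2. The list median was -2.52 (camera adjusted p = 0.00238; adjusted p = 0.536 with an estimated correlation). CHS1 and MYB12 were averaged over changing probes.

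**Figure D2:**
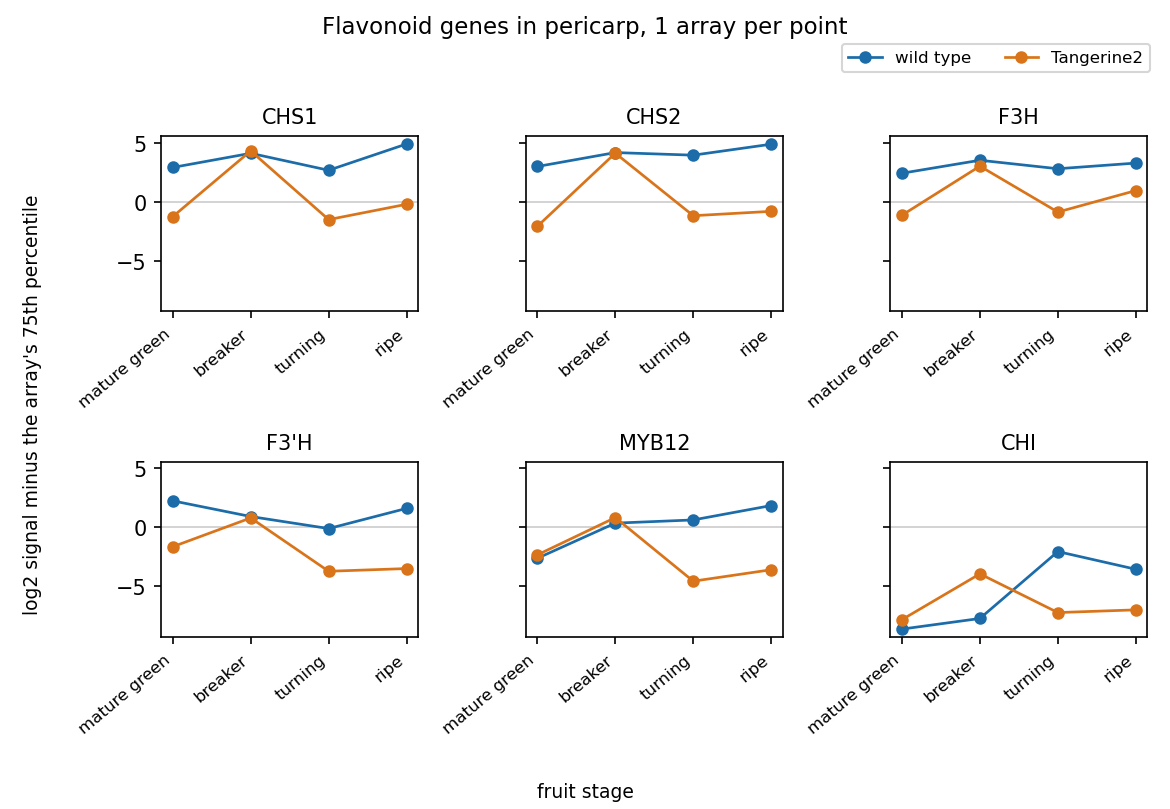
Log2 signal minus the array's 75th percentile (vertical) by stage (horizontal) for 6 flavonoid genes, with wild type in blue, Tangerine2 in orange and 1 array per point. CHS1 was 4.09 in wild type and 4.29 in Tangerine2 at breaker, and 4.88 and -0.23 in ripe fruit.

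Other lists called between genotypes, where an effect of the slide could not be separated, had smaller shifts. Ribosomal proteins had a median of -0.15 (camera adjusted p = 0.00238; adjusted p = 0.673 with an estimated correlation) with 1 member lower, the L15 record, against 2 adjusted over the list alone. Heat shock proteins had a median of -0.33 (0.0108; adjusted p = 0.536 with an estimated correlation), with vis1 at -3.01 lower and a small heat shock record at 2.19 (at least 1.03-fold) higher adjusted over the list alone. Histones had a median of -0.21 (0.0265; adjusted p = 0.673 with an estimated correlation), lost without breaker (0.374), without turning (0.0638) and with quantile normalization (0.0712). Epidermis and cuticle genes had a median of -1.99 (0.0265; adjusted p = 0.536 with an estimated correlation) and seed contents, mostly near the floor, 0.80 (0.0283; adjusted p = 0.536 with an estimated correlation); both were lost without mature green (0.062 each), without ripe (0.0787 and 0.0918) and with quantile normalization (0.117 and 0.245).

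The 13 measured members of the carotenoid pathway, without CRTISO, were not called between genotypes as a list. Their median was -0.12 (camera adjusted p = 0.199), and CYCB at 0.97 and VDE at -1.18 did not pass. LOXC at -2.02 (at least 2.75-fold) was lower and GAD3 at 2.19 ± 0.37 (at least 1.13-fold) higher adjusted over the list alone, in lists with medians of 0.09 for volatiles (0.466) and 0.46 for sugars (0.373). Medians were 0.21 for carotenoid cleavage (0.571), -0.18 for MEP and prenyl supply (0.373), 0.13 for ethylene (0.619), 0.09 for regulators (0.608), -0.19 for softening (0.571), 0.28 for light harvesting (0.373) and 0.37 for pathogen and wound genes (0.645). All of these ran in the lower direction except sugars and light harvesting, against a median of all accessions of 0.18. The direction differed from the sign of the median for cleavage, ethylene, regulators, volatiles and pathogen genes. For MEP and prenyl supply it differed from that of the mean, 0.17. Cleavage and pathogen medians lay above 0.18, so the median of all accessions does not account for their direction. Camera compares test statistics rather than log2 differences. The mean was -0.09 for cleavage and -0.22 for volatiles. With quantile normalization the median of all accessions was 0.00 and light harvesting was called (0.0294).

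Stage by stage, single arrays asked when the genotypes part. At mature green several ripening genes were higher in wild type: RIN was 0.55 against -3.74 in Tangerine2, the ethylene-response gene E8 0.02 against -4.70, expansin EXP1 0.63 against -3.19 and histidine decarboxylase hdc 0.15 against -5.36. NOR went the other way, at -3.39 against -2.21, as did PG-2a, at -2.80 against -2.22. ACS4 and PG2A, averaged over changing probes, were lower in wild type by 0.93 and 1.29, while further ACS4 and polygalacturonase records, below detection, were -5.30 against -7.24 and -6.90 against -8.31. At turning and ripe the jasmonate repressor JAZ1, lower at breaker (-4.62), was higher in Tangerine2 by 7.46 and 6.20 and the defence regulator Pti5 by 5.81 and 6.21, while the defence proteins PR1, at -5.46 and -5.95, and P6, at -5.63 and -5.89, were lower. APRR2, a pigment regulator, was 2.54 in ripe Tangerine2 and -2.81 in wild type. Each of these values is 1 array, with slide and genotype inseparable, and E8 and hdc were averaged over changing probes.

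Further large single-array differences between genotypes were UDP-glucose pyrophosphorylase at 5.65 at mature green and 5.87 at breaker, a chitin-binding lectin at -8.19 at mature green and an extensin at -6.63 at breaker. At breaker a photosystem I reaction center V record was at -5.81 and a photosystem II 10 kDa record at 3.58. Endochitinase 1 was higher by 5.17 in ripe Tangerine2, and hsc70.3 was lower, at -5.74. TUB8 and DXS1 differed by 6.90 and 4.90 at mature green and GRAS6 by 5.66 at ripe, but their averaged probes changed. At least 2-fold differences numbered 9193 at mature green, 7891 at breaker, 16784 at turning and 11790 at ripe. At turning 69.3% of these were higher in Tangerine2, against 51.5% among accessions measured on both arrays, and at ripe 61.5% against 50.6%.

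Flavonoid genes lay below every random list at 3 stages, with Tangerine2 minus wild type medians of -3.56 at mature green, -4.18 at turning and -5.10 at ripe (percentile 0 each), and 0.20 at breaker (percentile 64.22). The percentiles here take the genes of a list as independent, so they overstate how unusual a list of genes that move together is. Epidermis and cuticle genes had medians of -1.47, 0.43, -3.44 and -2.08 (percentiles 0.07, 91.39, 0 and 0.19). Light harvesting was at 0.65, 0.24, 0.25 and 0.03 (percentiles 100, 98.47, 87.31 and 29.59), softening at 0.82, 0.45, -0.16 and 0.00 (99.58, 99.12, 30.84 and 59.09) and sugars at 0.46, 0.68, 0.92 and 1.05 (96.26, 98.16, 92.88 and 98.23), while heat shock proteins were at -0.45, 0.29, -0.50 and -0.32 (percentiles 0, 99.63, 0 and 0.41). The carotenoid pathway was at -0.24, 0.01, -0.69 and 0.26 (percentiles 30.29, 42.92, 3.22 and 71.01). SGR1 was at -2.21, -0.48, 0.39 and 0.25.

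**Figure D3:**
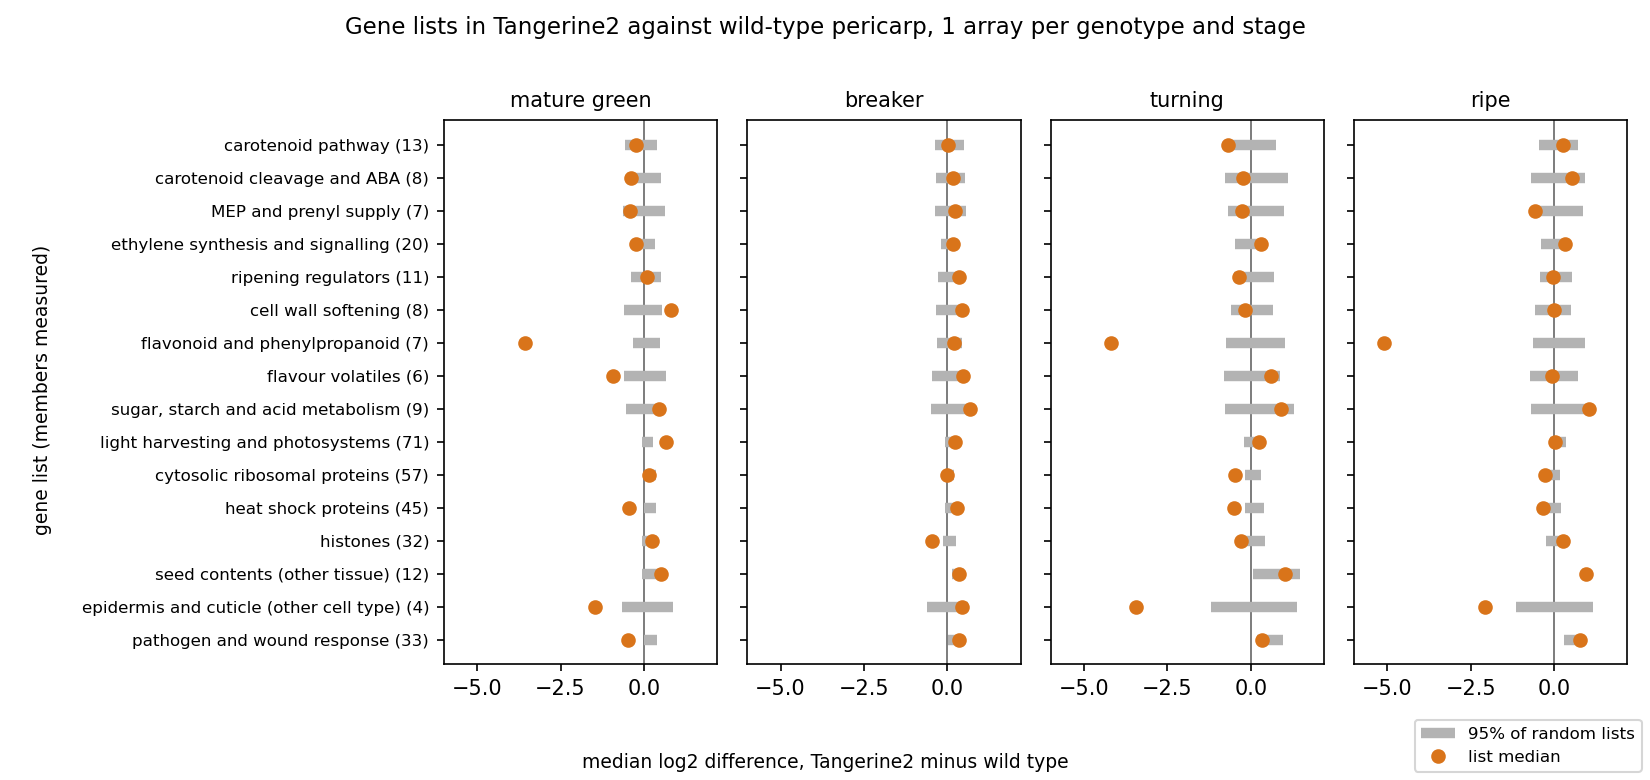
Median log2 difference of Tangerine2 minus wild type (horizontal, orange dots) of 16 gene lists at each of the 4 stages, with list sizes in brackets and grey bars for the middle 95% of random lists matched on mean signal. Flavonoid genes were at -3.56, 0.20, -4.18 and -5.10 from mature green to ripe.

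The slope comparison asked whether ripening ran differently in Tangerine2. No accession passed: 0 of 40387 in limma, with 2752 at an unadjusted p under 0.05. The smallest p belonged to a CLE family signalling peptide, whose slope was higher in Tangerine2 by 3.25 ± 0.23 per stage (adjusted p = 0.259). It was well above background on 0 Tangerine2 arrays (-8.12 to -6.94) and ran from 0.52 to -7.91 in wild type, so only the wild-type fall was measured. Among named genes, the further ones of the 5 smallest p-values in the higher direction were Acyltransferase 1 at 1.56, a KNOX homeobox factor at 1.05, the initiation factor eIF4B at 1.01 and a WRKY factor at 1.74. In the lower direction they were cystatin at -0.90, the ferredoxin SEND33 at -1.29, plastocyanin at -1.22, an aquaporin at -1.60 and Remorin 1 at -1.18 (adjusted p = 0.713 each). The KNOX factor, eIF4B and Remorin 1 were well above background on 0, 1 and 0 Tangerine2 arrays, and the aquaporin was averaged over changing probes. Light harvesting genes had a median slope difference of -0.17 (camera adjusted p = 0.00104; adjusted p = 0.934 with an estimated correlation), lost without the wild-type mature green array (0.646) or the Tangerine2 ripe array (0.112). Ribosomal proteins had -0.15 (2.58e-05; adjusted p = 0.934 with an estimated correlation), lost without the Tangerine2 mature green array (0.17). EXP1 at 2.40 ± 0.57 was higher adjusted over its list alone.

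Within Tangerine2, single arrays asked what changed during its ripening. Histidine decarboxylase hdc was higher at least 1170-fold at breaker than at mature green, 486-fold at turning and 485-fold at ripe, with 12 of its 18 probes below detection at mature green. The mannanase MAN4A was higher at least 583-fold at breaker, AAT at least 653-fold and ER1 by 9.39 in ripe fruit. PR1 at -9.77 and P6 at -10.45 were lower in ripe fruit, as was the ethylene-induced P1(p14), at least 2250-fold. Chlorophyll a/b protein records 3C and 1B were lower at least 584-fold and by 9.25. At least 2-fold differences numbered 10520 of 29328 at breaker, 11797 of 28638 at turning and 12327 of 28387 at ripe. Light harvesting genes had medians of -0.26, 0.00 and -0.70 (percentiles 3.69, 42.6 and 0), which split into -0.36, -1.06 and -1.50 for nuclear records and -0.01, 0.55 and -0.22 for plastid records (percentiles 1.93, 0 and 0 against 44.51, 98.75 and 7.42). Softening genes had medians of 3.05, 4.64 and 4.10 (percentile 100 each).

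Within wild type the same question gave PG2A higher by 10.03, 10.49 and 10.54 at breaker, turning and ripe, and NOR by 5.41 at turning. A photosystem I reaction center V record was higher by 5.96 at breaker, unlike the photosynthesis genes that fell. A photosystem II 10 kDa record was higher by 6.86 at turning. It has 2 probes, and which of them were averaged on each wild-type array is not known. PPCK2, a kinase of phosphoenolpyruvate carboxylase whose averaged probes changed, was higher by 5.03 at breaker and the hexose transporter HT1 was lower, at -6.03 at breaker and -7.79 at turning. In ripe fruit the lipid-transfer protein ltpg1, TGAS118 and LeGLO2 were lower, at -8.11, -8.09 and -7.22. At least 2-fold differences numbered 9742, 11906 and 14298 of 40387. The carotenoid pathway had medians of 0.50, 1.00 and 1.21 in wild type (percentiles 97.39, 99.86 and 99.91) and 0.06, 0.52 and 0.08 in Tangerine2 (46.5, 90.49 and 56.1). These are not like measures, since wild type is 13 members of the value table and Tangerine2 is 12 members of the scanner files with all probes averaged, and on the value table the slopes were not apart (camera adjusted p = 0.822).

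Large changes of ripening went mostly the same way in both genotypes. Across genes, which are not independent, the change from mature green to ripe correlated at 0.63 between genotypes, and at 0.709 among accessions above detection. The correlations over all accessions were weaker at breaker and turning, at 0.477 and 0.48. Of 3255 accessions at least 4-fold changed in both, 3092 (95%) moved in the same direction. The share was 90.6% of 1794 at breaker and 88.7% of 2231 at turning.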

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

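The test of the flavonoid genes under quantile normalization and the counts over other splits of the arrays were chosen only after the results were seen, as were a corrected keyword in the cuticle test and the limit to accessions above detection in the tests on mature green fruit.

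Light harvesting and photosystem genes, which run photosynthesis, and cytosolic ribosomal proteins had lower slopes over the stages in Tangerine2 than in wild type. The median differences of slope were -0.17 and -0.15, and a test of the difference between genotypes singled them out (camera adjusted p = 0.00104 and 2.58e-05). Both calls were lost with an estimated correlation (adjusted p = 0.934 each). For single genes the real count was 0, so all 35 splits of the 8 arrays were bound to give as many and say nothing about chance; the highest of the others was also 0. In limma 2752 accessions had an unadjusted p under 0.05.

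The lower flavonoid genes in Tangerine2 at mature green, turning and ripe, but not breaker, were weighed against the scaling of the table and the share of epidermis, where these genes are largely expressed. After quantile normalization the list medians were -3.71, -4.16 and -4.91 at the 3 stages and 0.00 at breaker, which argues against the scaling as the whole cause. Less epidermis in the fruit pieces stays open. The 7 further records matched by cuticle and wax keywords gave -0.21 for the 3 stages minus breaker (95% interval -4.17 to 0.49), with wide spread. That value leans on 3 flat GPAT records, whose product name alone does not tie them to the cuticle. GPAT and LE16 had several records each, which the interval treats as independent genes. At turning the lipid-transfer protein LE16 was at -5.16 and ltpg1 was 1.28 in wild type and below the limit of -4.97 in Tangerine2, while 3 records of acyltransferase GPAT lay between -0.73 and 0.01 at all stages and a GPAT4 record was at 0.62 at mature green and 4.37 at breaker, then below detection in both genotypes. A keyword that had matched an unrelated gene was corrected after a first result, with the question undecided both times. A genotype effect and the slide also stay open and cannot be told apart in this design. A slide effect alike on all 4 Tangerine2 arrays would also have shown at breaker, where the list median was 0.00, on 1 array per genotype. The Tangerine2 breaker array correlated more with each wild-type array than with any other Tangerine2 array. Whether the breaker stage or that 1 array was the exception therefore cannot be told.

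Higher RIN, E8, EXP1 and hdc in wild-type than in Tangerine2 mature green fruit would follow if the wild-type fruit were further into ripening. Over 566 accessions at least 8-fold higher in wild-type breaker than mature green fruit, wild type minus Tangerine2 was -0.35 at mature green (95% interval -0.43 to -0.31), and that minus the breaker difference was -1.19 (-1.43 to -0.90), which lay past the bounds set in advance against this cause and against a constant offset. These bounds exclude nothing: the accessions were chosen as low on the wild-type mature green array and high on the wild-type breaker array, and the same arrays enter both values, which pushes both down whatever the cause. Among the 296 above detection, chosen in the same way, the values were 0.21 (-0.11 to 0.55) and 0.15 (-0.16 to 0.52), which leaves both open. All these intervals resample accessions, which are not independent, on 1 array per genotype and stage. They hold no spread between fruit or arrays. For 5 ripening genes that rose (RIN, NOR, PG2A, ACS2 and ACS4) the median was -0.93, with PG2A and ACS4 averaged over changing probes. PG-2a, a further polygalacturonase record and so not separate from PG2A, was lower in wild type, at -2.80 against -2.22. Of other large risers, ER1 was higher in wild type, at -1.17 against -4.83, as was the MADS-box factor LOC778231, at 1.13 against -3.02. These genes do not decide the cause.

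The 14 accessions apart between genotypes at all stages may include sequence differences under a probe. Other records of the same product existed for 1 of them, L15, and their median absolute difference was 0.17 over 3 records, too few to decide for the set. Among 32 splits of the 8 arrays that could be fitted, 3 gave as many accessions, the real split included. The real count was 14 and the highest other 20. Both other splits keep the mature green arrays together and the breaker arrays together, so they carry the genotype difference at turning and ripe alone. With stage in the fit they are the same comparison with its sign reversed. The splits therefore cannot decide about chance, which was not excluded.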

How the results depend on the processing

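The mean filter, values raised to the detection limit and the 1-probe filter were chosen only after the results were seen. No list or named gene passed in the opposite direction under an alternative, but the balance of rises and falls did change. Of 216 list results under alternatives 154 kept their side of the threshold and 62 became weaker; of 1847 for named genes 1156 kept it and 691 became weaker; of 712 single-array values 41 moved. The 14 genotype accessions became 56 with signal well above background on all 4 Tangerine2 arrays (9 shared), 23 with the mean filter (10 shared), 5 with values raised (3 shared), 26 with a trended robust prior (13 shared), 90 without stage (13 shared) and 0 to 4 with a stage left out. The 2077 ripe accessions became 1233 with quantile normalization (1092 shared), 573 with values raised, 6133 with linear stage and 0 to 1683 with an array left out. The 330 at breaker became 29 with quantile normalization, 36 well above background on all 4, 73 with the mean filter, 162 raised, 138 without genotype and 0 to 114 with an array left out. The 733 at turning became 237, 292 (all 4), 270 (raised), 473 (no genotype) and 0 to 371. The slope count of 0 (limma) became 6 with values raised, none with a named product; it stayed 0 for later minus earlier stages (3632 at an unadjusted p under 0.05). The cause was not tested, except that the filters test fewer genes and fits with an array left out have fewer samples.

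Single-array counts for Tangerine2 became 5284, 7701 and 7626 at breaker, turning and ripe with normexp, and 21212 at ripe with no filter. For wild type they became 5129, 6708 and 8469 with the mean filter and 5566, 7143 and 8955 raised. Between genotypes they became 3999, 3552, 7586 and 6322 with the mean filter, 4404, 3649, 7763 and 6130 raised, and 11109 at turning with signal well above background on at least 1 array. Lists called fell from 6, 6, 7, 3 and 2 (genotype, ripe, breaker, turning, slope) to 0 each with an estimated correlation, and ranged over 4 to 6, 3 to 6, 4 to 9, 2 to 5 and 1 to 5 with a stage or array left out. Beyond scaling, the share of higher genes went from 33.8% to 63.9% among ripe passing accessions with linear stage, from 27.6% at breaker to 61.4% without the wild-type mature green array, 61.1% well above background on all 4 and 56.2% with the mean filter, from 64.3% to 20% between genotypes with values raised, and from 46.6% to 58.1% and 68.7% in ripe Tangerine2 with both arrays well above background and with no filter. Scaling moved it too: with quantile normalization from 69.3% to 50.9% at turning and from 61.5% to 50.9% at ripe between genotypes, with median centring from 33.8% to 49.0% among ripe passing accessions, from 30.0% to 40.3% at turning, from 50.1% to 60.7% and 53.4% to 68.5% in wild type at turning and ripe and from 46.6% to 57.9% in ripe Tangerine2, and with normexp from 48.4% to 63.4% and 46.6% to 59.6% in Tangerine2 at turning and ripe.

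Each probe on its own was not run, nor the brightest probe outside the Tangerine2 stage comparisons, because the value table holds 1 value per accession. With an array left out, the lone array of its stage is assumed to vary like the others. No paired analysis was possible because each group has 1 array, so replicate numbers pair nothing; the genotype fit already compares genotypes within stages. Signal over background limits the dim genes: 16378 accessions had a mean below the highest detection limit.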

Other observations

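The grouping of accessions by product name and its tests were chosen only after the results were seen, and lie outside the lists.

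Of 7 records of phosphoenolpyruvate carboxylase, which fixes bicarbonate into the organic acids that young fruit store, 3 fell in ripe fruit and 0 rose. One record fell by 5.96 (adjusted p = 0.0115), from 1.32 at mature green to -4.59 at ripe in wild type and from 1.85 to -4.14 in Tangerine2. Further records fell by 3.28 (adjusted p = 0.0166) and 3.14 (adjusted p = 0.035), while 3 others were at 0.45, 0.41 and 0.43, among them the brightest record, so the records split. Of 7 product groups with at least 5 measured members, this was the group called by camera (7 members, median -2.49, adjusted p = 0.0396; adjusted p = 0.456 with an estimated correlation). Between genotypes its median was -0.53 (adjusted p = 0.0533).

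Fructose-bisphosphate aldolase, shared by glycolysis and the Calvin cycle, had a median of -1.87 (adjusted p = 0.18) and 0 members passed in limma. RNA polymerase records had a median of 1.29 (adjusted p = 0.191) and the sty-l protein 0.98 (adjusted p = 0.18). Peptidyl-prolyl isomerases, ubiquitin hydrolases and ubiquitin carrier proteins were at 0.18, 0.26 and 0.19 (adjusted p = 0.949 each).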
